A study of Zea mays with 115 samples.

How the data were processed

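Small RNAs of maize seedlings were sequenced from 115 libraries of 105 inbred lines. Per the labels' protocols, all lines were grown together for 7 days in a randomized layout, whole seedlings of 4 plants per entry were pooled, total RNA was isolated with a mirVana kit, libraries were made with the NEXTflex Small RNA kit v2, and reads of 50 nt were taken on an Illumina HiSeq. Per the submitters' processing notes, adapters were trimmed with Trim Galore. Aligner and genome build are not given in the sources used here. The deposited table holds, per its name, RPM values, reads scaled to a common library total, of each distinct sequence after quantile normalization by the authors, for sequences that reached 1 RPM in at least 1 library. It was checked that all 477193 sequences met that minimum (smallest maximum 1.00 RPM) and were 18 to 40 nt long.

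In every library the values were whole multiples of a step of its own, within 0.01 of a step, and the largest value was 23390044 steps in each of the 115 libraries. The values are therefore rank means that quantile normalization gave, divided by a library total, and no reads can be recovered from them. Depth per library is unknown and no counting interval or floor is given. A value of 0 means only that the sequence is listed at 0, and 28.6% to 83.1% of all sequences were at 0 in a library. Ties among low values appear to have been broken by the order of the sequences in the table. Within the lowest 20% of values above 0, the Spearman correlation of value and alphabetical order was negative in all 115 libraries (median −0.281, from −0.9999 to −0.0621). Ranks among rare sequences may therefore carry this order as well, and a preference for certain 5′ bases was not tested. Because each library was given the same set of values, a shift of most sequences at once cannot be seen.

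Lines were assigned to pools by the first letter of their names. The design text names 64 Dent and 41 Flint lines, and only the letters p with s and f with l add up to these numbers, so Dent rests on p and s and Flint on f and l. This mapping rests on counts alone. Names ending in r were read as second libraries of 10 lines, 5 in each pool, and both libraries of a line were averaged on the log2 scale before any test between groups. What the letters within a pool stand for was not stated. No batch was given by the labels. The share of RPM that matched the 5′ adapter of the kit ranged from 0.00224% to 2.08% over libraries, and although this range was continuous, a boundary of 0.15%, placed between libraries at 0.148% and 0.195%, was used to divide them, by the mean of both libraries where a line had a repeat, into 60 lines of low and 45 of high share, 40 and 24 in Dent and 20 and 21 in Flint. This division was set after the data were seen and is used as a stand-in for a preparation batch. The pools did not differ past the threshold in adapter share (0.301% ± 0.469 in Dent, 0.347% ± 0.423 in Flint), in sequences at 0 (48.8% ± 10.2 and 49.5% ± 9.68) or in 7 other measures of library quality (smallest adjusted p 0.319, permutation tests).

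Groups, tests, lists of miRNA families and the rule for named sequences were chosen before the data were examined. Sequences at 1 RPM or more in at least 11 lines, 145521 in number, were compared on log2(RPM + 1) with limma (version 3.58.1 in R 4.3.3), with trended eBayes, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on the log2(RPM + 1) scale and understate changes of rare sequences. The p and s series and the f and l series were compared in a model with 4 group means. Named sequences are, for each of 21, 22 and 24 nt and each direction, the 3 with the largest log2 difference among those called, at a mean of 10 RPM or more in the higher pool, with the same sign in p against f and in s against l lines. Named families are those with a mean of 1 RPM or more. The list held 30 families with 54 mature sequences written from background knowledge, of which 24 families and 38 sequences had exact matches in the table. Family values are sums over exact matches. They were grouped into development, nutrient and copper, and silencing pathway lists, and a list of structural RNA held fragments of rRNA and tRNA. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry.

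Length shares, families, library quality and correlations were tested with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). For the repeats, second libraries of a pool were reassigned at random to lines of that pool, each line used at most 1 time. All p-values treat lines as independent, though lines of a breeding programme can be related. Pooled plants give 1 value per library, so the spread between libraries holds both line and preparation. On simulated shifts placed in the real values with lines shuffled, for Dent against Flint, limma called 58.2% of sequences shifted by 0.5, 97.0% of those shifted by 1 and 100% of those shifted by 2 log2 units, and 1 of the unshifted sequences among 145521 in the test. The shifts were added on the log2(RPM + 1) scale, also to lines at 0, so these shares overstate what is found for rare sequences. The count of unshifted sequences rests on 1 shuffle, and a random split of the lines used further below called 783.

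Alternatives were other pseudocounts (0.1 and 0.5 RPM), no filter and a filter of 53 lines, first libraries alone, untrended eBayes, limma on ranks, rescaled totals, single series, family sums over the first 18 bases, length shares over distinct sequences or without the 100 most abundant, and Pearson's correlation. Added after the data were seen were the adapter share and the share of sequences at 0 as covariates, either adapter class alone, leaving out the 5 lines with most sequences at 0, family levels relative to other families, s against l lines for families (exact permutation test over all splits), and other settings for the lists. Positions in the genome were not analysed here.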

Results

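Small RNAs were measured in seedlings of 105 maize inbred lines, 64 from the Dent pool and 41 from the Flint pool, the breeding pools whose lines are crossed with each other to make hybrids. The study set out to relate such measurements to hybrid performance, and the comparison its design implies is that between the pools. Plants were 7 days old and 4 plants were pooled per entry. The line names fell into 4 series, p (52 lines) and s (12 lines) in Dent and f (35 lines) and l (6 lines) in Flint, and 5 lines of each pool had a second library, so that 115 libraries were compared. The deposited table listed 477193 distinct sequences of 18 to 40 nt in quantile-normalized RPM, reads scaled to a common library total, and the listed values summed to between 665022 and 774926 RPM per library. Read depth was unknown, since the values are rank means and not reads. Between 42105 and 80727 sequences per library reached 1 RPM. Only 4263 sequences reached 1 RPM in every line, while 330228 (69.2%) did so in under 11 lines. Positions in the genome were not analysed here, so sequences are given by their bases. Lines of a breeding pool can be related, and the tests below treat them as independent.

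The size classes of plant small RNAs come from different Dicer-like enzymes, the 21-nt class holding most miRNAs and the 24-nt class the siRNAs that direct DNA methylation. None of the 7 classes differed between the pools in its share of summed RPM. The 24-nt class made up 10.4% ± 2.24 (SD, n = 64) in Dent and 10.0% ± 1.42 (SD, n = 41) in Flint. The 22-nt class made up 8.85% ± 2.15 and 9.31% ± 1.62, and the 21-nt class 8.66% ± 2.34 and 8.26% ± 1.30. The smallest adjusted p over the classes was 0.749 (two-sided permutation test, Benjamini-Hochberg over 7 classes). Fragments of 25 to 40 nt were the largest class in both pools, at 42.5% ± 14.01 in Dent and 43.4% ± 8.04 in Flint. Within each pool the 22-nt share rose with the 24-nt share across lines. Pearson's r was 0.52 in Dent (permutation p = 2e-05) and 0.81 in Flint (p = 1e-05, the smallest that 100000 resamples can give), and Spearman's rho was 0.70 and 0.81 (p = 1e-05 for both). Without the 2 lines farthest from the median, r was 0.50 and 0.80. The lines were divided at 0.15% of RPM by their share of 5′ adapter sequence, a continuous measure, and rho was 0.72 and 0.72 in Dent lines of low and high adapter share and 0.77 and 0.90 in such Flint lines. Shares of a common total move with its biggest class, and over the 15 pairs of classes up to 24 nt the median rho was 0.70 in Dent and 0.54 in Flint. With the share of 25 to 40 nt taken off, rho was 0.50 and 0.70, against medians of −0.22 and −0.05 over the pairs and the highest of the 15 in both pools, a check chosen after the data were seen.

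**Figure D1:**
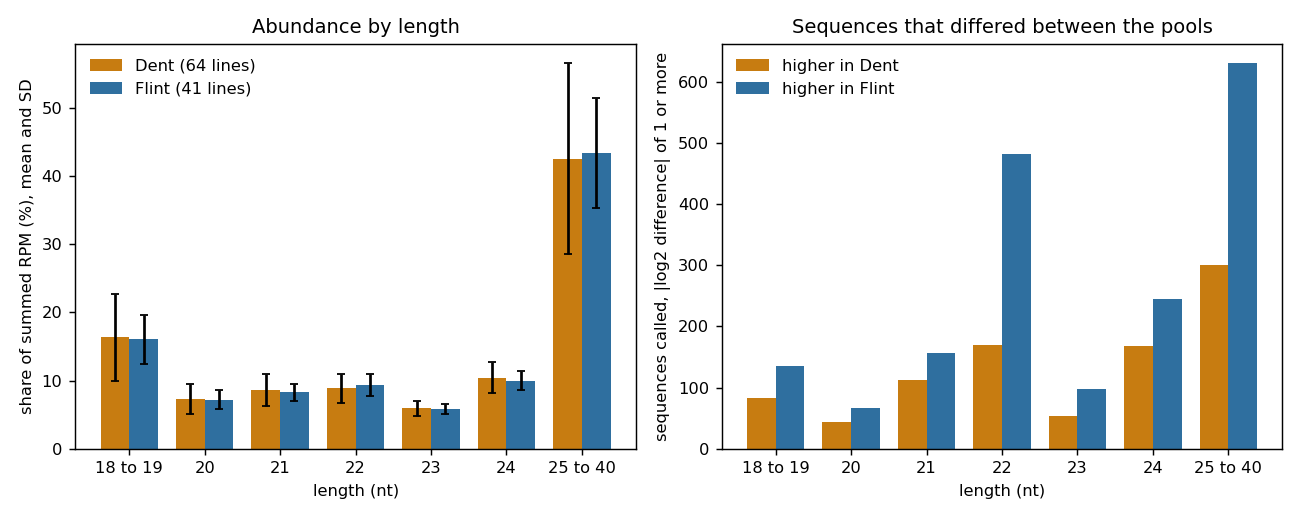
Left, mean share of summed RPM (percent, bars start at 0, error bars SD over lines) in each length class for 64 Dent and 41 Flint lines. Right, number of sequences per length class that limma called with an absolute log2 difference of 1 or more; no class differed in share past the threshold, while 482 sequences of 22 nt were higher in Flint, 2.85 times the number higher in Dent (1.37 times in lines of low and 5.804 times in lines of high adapter share).

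Individual sequences differed widely between the pools even though the classes did not. Of 145521 sequences tested, 15893 were higher in Dent and 18135 were higher in Flint (limma on log2(RPM + 1), Benjamini-Hochberg adjusted p under 0.05), together 23.4% of those tested. A difference of at least 1 log2 unit was reached by 929 sequences higher in Dent and 1812 higher in Flint. The 22-nt class was called most often, with 39.1% of its 23031 tested sequences, followed by the 24-nt class with 31.7% of 25962 and the 21-nt class with 27.6% of 9949. Among 22-nt sequences with at least 1 log2 unit, 482 were higher in Flint, 2.85 times the number higher in Dent. This ratio was 1.37 in lines of low adapter share and 5.804 in lines of high adapter share (1097 and 189), 1.46 among sequences at 1 RPM in at least 53 lines and 1.47 with a pseudocount of 0.1. Among 24-nt sequences of any size of difference, 5028 were higher in Dent and 3209 in Flint, an excess that turned round in lines of high adapter share (2248 and 2983), in s against l lines (52 and 965) and among sequences at 1 RPM in at least 53 lines (413 and 441). It also turned round over all lines with at least 1 log2 unit, where more 24-nt sequences were higher in Flint than in Dent. Many of the 2741 larger calls overlapped: joined by 18 shared bases, they formed 1233 groups, the biggest with 210 sequences higher in Dent and 89 higher in Flint. When the 12 s lines were compared with the 6 l lines alone, 390 of the 2741 were called in the same direction and 212 had the opposite sign. In lines of low adapter share 2362 (86.2%) were called in the same direction and 36 had the opposite sign, and in lines of high adapter share 94.2% were called. On the log2(RPM + 1) scale the differences of rare sequences are understated, and the number past 1 log2 unit therefore rose to 10412 and 11709 with a pseudocount of 0.1.

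Several of the sequences that differed most came as pairs that differed by 1 base, with the members higher in opposite pools. Substitutions are written with the base of the first sequence, the position from 1 at its 5′ end, and the base of the second. Of the 21-nt sequences, CAAGAAGGGTTCTGACAGCGG was at 38.5 RPM ± 33.4 (SD, n = 64) in Dent and 3.26 ± 13.2 (n = 41) in Flint, a log2 difference of 4.0 ± 0.35 (SE). Its partner by A15G, CAAGAAGGGTTCTGGCAGCGG, was at 1.82 RPM ± 7.53 in Dent and 20.7 ± 11.2 in Flint (log2 difference −3.67 ± 0.22), and 94 of the 105 lines had just 1 of the pair at 1 RPM or more. TCAGAAAATATGAACTTGAGA was higher in Dent (log2 difference 3.73 ± 0.26), where 62 lines reached 1 RPM against 3 Flint lines. GAGAGAAAAGAGGACGTGGTA was higher in Flint (−3.74 ± 0.22), where 39 lines reached 1 RPM against 5 Dent lines. A further 21-nt pair differed by C7T and T21C. GCTCACCCTCTATCTGTCAGT was at 81.1 RPM ± 71.8 in Dent and 31.3 ± 69.4 in Flint, and GCTCACTCTCTATCTGTCAGC at 7.76 ± 35.6 and 126 ± 164.7. The adjusted p-values of these 6 sequences in limma lay between 3.45e-29 and 1.39e-11.

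Of the 22-nt sequences, TTACTTTGAGGAAAATACCCGA was at 0.131 RPM ± 0.693 in Dent and 21.0 ± 19.6 in Flint (log2 difference −3.76 ± 0.19), and CAGATACTTTTGGGGCACCTGG at 0.0952 ± 0.487 and 13.3 ± 8.43 (−3.36 ± 0.16). ACACCAGAATCCATCGTCGAGA was at 10.0 RPM ± 6.87 in Dent and 1.16 ± 4.06 in Flint (2.73 ± 0.23), and its partner by A6C, ACACCCGAATCCATCGTCGAGA, which lies outside the rule for named sequences and was picked after its values were seen, had a log2 difference of −2.92 ± 0.22. AGGATGCTGACGCAATGTGATT was higher in Dent (93.4 RPM ± 79.6 against 20.1 ± 25.3) and its partner by A1C, CGGATGCTGACGCAATGTGATT, was higher in Flint (29.5 RPM ± 23.6 against 3.49 ± 14.5). Both members of this pair reached 1 RPM in 49 lines. TCCGTCCACGCCCGGTCGTACT was higher in Dent by 2.99 ± 0.35. Among 24-nt sequences the same 5′ ends recurred: TCCGTCCACGCCCGGTCGTACTCA was at 64.5 RPM ± 102 in Dent and 4.28 ± 17.7 in Flint, and its partner by T1A, ACCGTCCACGCCCGGTCGTACTCA, at 31.8 ± 56.9 and 59.1 ± 36.7. In 27 lines both of these reached 1 RPM. TTCCGTCCACGCCCGGTCGTACTC (2.21 ± 0.29) and AGGATGCTGACGCAATGTGATTTC (1.78 ± 0.21) were also higher in Dent. TTGGCTAACTGAATTCTCTGATAG was at 0.0492 RPM ± 0.223 in Dent and 12.3 ± 11.5 in Flint, and ATTATATTTGTAGAGTGGACCGGG was higher in Flint by 2.57 log2 units (Dent minus Flint −2.57 ± 0.30). The named 22- and 24-nt sequences whose bases recur belong to the biggest and the next biggest group of overlapping calls between the pools. Members of both groups range from 18 nt to far above 24 nt. Length alone therefore does not show these named sequences to be products of a Dicer-like enzyme, and their origin was not tested. The rule for named sequences required the same sign in p against f lines and in s against l lines, and with s and l lines alone 11 of the 18 were not called. Differences there were far smaller for some, at 0.40 for GCTCACCCTCTATCTGTCAGT (3.67 over all lines), −0.33 for CGGATGCTGACGCAATGTGATT (−3.40), 0.70 for AGGATGCTGACGCAATGTGATT (2.54) and 0.19 for AGGATGCTGACGCAATGTGATTTC (1.78).

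Of 30 listed miRNA families, 24 had a mature sequence in the table and 6 of these differed between the pools. On the nutrient and copper list, 3 of 7 families were higher in Dent, 1 was higher in Flint and 3 were not called. miR398, which targets copper/zinc superoxide dismutase, was at 121 RPM ± 114 (SD, n = 64) in Dent and 39.9 ± 39.6 (SD, n = 41) in Flint, a log2 difference of 1.51 ± 0.23 (SE; adjusted p = 0.00012 over the list alone, two-sided permutation test). miR408, which targets copper proteins such as plantacyanin and laccases, was at 133 RPM ± 117.4 in Dent and 63.8 ± 49.4 in Flint (0.91 ± 0.22, adjusted p = 0.00136). miR399, a regulator of phosphate uptake through PHO2, was at 4.0 RPM ± 4.66 and 1.83 ± 2.07 (0.68 ± 0.19, adjusted p = 0.00462). miR397, another miRNA of laccases, went the other way, at 3.66 RPM ± 7.36 in Dent and 13.7 ± 23.6 in Flint (−1.51 ± 0.32, adjusted p = 0.00012). Outside the nutrient and copper list, miR159, which targets GAMYB transcription factors, was at 1442 RPM ± 1066 in Dent and 915 ± 639 in Flint (0.57 ± 0.18, adjusted p = 0.0123). miR168, which targets AGO1, was at 566 RPM ± 580 and 331 ± 262 (0.60 ± 0.22, adjusted p = 0.0384), and its call was lost with first libraries alone (adjusted p = 0.0750) and when all sequences with its first 18 bases were summed (0.0727).

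**Figure D2:**
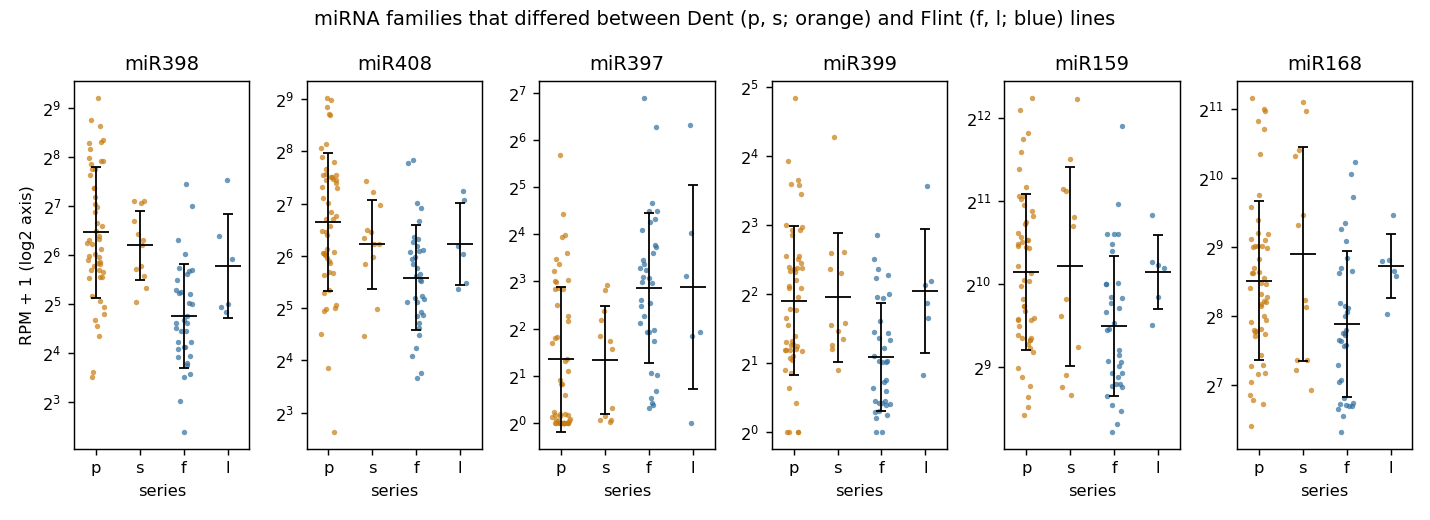
Level of the 6 miRNA families that differed between the pools (RPM + 1 on a log2 axis), 1 point per line, by series of lines (p and s Dent, f and l Flint); black marks are means on the log2 scale and bars 1 SD. miR398 averaged 130 RPM in p, 80.2 in s, 34.95 in f and 68.8 in l lines, and miR397 averaged 3.97, 2.31, 12.98 and 17.9 RPM.

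In the 12 s against the 6 l lines, an alternative chosen after the data were seen, 0 of the 24 families were called and 1 had an unadjusted p under 0.05 (exact permutation test). miR408 averaged 84.8 RPM in s and 84.04 in l lines (log2 difference 0.11), miR398 80.2 and 68.8 RPM (0.45), and miR399 3.94 and 3.89 RPM (−0.08, the opposite sign). For miR159 the difference was 0.02, for miR168 0.11 and for miR397 −1.48. Whether these differ from those of p against f lines was not tested.

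In lines of low adapter share alone, miR398 (log2 difference 1.77, adjusted p = 0.00024) and miR408 (1.13, adjusted p = 0.00912) were called, and miR397 (−0.97, adjusted p = 0.101) and miR168 (0.28, adjusted p = 0.357) were not. miR528, another copper-linked miRNA, was called in these lines (1.02, adjusted p = 0.00912) but not over all lines (0.30, adjusted p = 0.362), and its difference had the opposite sign at high adapter share (−0.48). In lines of high adapter share, miR398 (1.25, adjusted p = 0.00264), miR397 (−2.09, adjusted p = 0.0012) and miR168 (1.16, adjusted p = 0.0386) were called and miR408 was not (0.49, adjusted p = 0.305). miR159 and miR399 were called in neither class, with differences of 0.47 and 0.66 at low and 0.79 and 0.81 at high adapter share. The remaining 16 families of 1 RPM or more were not called over all lines. Abundant ones among them were miR166 (807 RPM ± 576 in Dent and 656 ± 393 in Flint), miR156 (675 ± 477 and 570 ± 397), miR169 (467 ± 375 and 400 ± 253), miR167 (364 ± 230 and 311 ± 150), miR396 (331 ± 257 and 425 ± 228), miR390 (314 ± 225 and 248 ± 131) and miR528 (726 ± 564 and 588 ± 455). Adjusted p-values were 0.0843 for miR396 and 0.168 for miR160, and from 0.209 to 0.978 for the other 14: miR156, miR162, miR164, miR166, miR167, miR169, miR171, miR319, miR390, miR394, miR444, miR528, miR529 and miR827. Set relative to the mean of the other named families, the 6 calls kept their direction, and miR396 (−0.76, adjusted p = 7.33e-05), miR394 (−0.33, adjusted p = 0.00726) and miR164 (−0.31, adjusted p = 0.0497) were lower in Dent as well. The miR396 sum left out a sequence at a mean of 2215 RPM that equals a listed miR396 form without its first base. Sums over the first bases of listed forms left it out too. The miR396 values are therefore for the listed forms alone and do not give the level of the whole family.

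Over the 35 listed miRNA sequences that entered the limma test, 7 were higher in Dent and 2 in Flint, both over all sequences tested and adjusted over the list alone. This share is near that of all 145521 sequences tested (23.4%) and of all 21-nt sequences tested (27.6%). The listed miRNAs were thus not called more often than sequences in general. Within the miR156 family, whose targets are SPL transcription factors, the abundant member TGACAGAAGAGAGTGAGCAC did not differ (631 RPM ± 447 in Dent and 555 ± 384 in Flint, adjusted p = 0.763). The member TGACAGAAGAGAGCGAGCAC was at 41.2 RPM ± 33.8 in Dent and 11.7 ± 18.7 in Flint (log2 difference 2.76 ± 0.29, limma adjusted p = 1.2e-13). A form with the substitution A12G, TGACAGAAGAGGGCGAGCAC, lies outside the list and was picked after its values were seen. It was at 18.4 RPM ± 19.2 in Flint and 0.450 ± 2.69 in Dent (−2.87 ± 0.29, limma adjusted p = 4.1e-15). It reached 1 RPM in 27 of 35 f lines, 0 of 6 l lines, 2 of 52 p lines and 0 of 12 s lines. Of all 105 lines, 94 had just 1 of both forms at 1 RPM or more and 11 had both. A miR396 sequence, TTCCACAGCTTTCTTGAACTG, was higher in Flint (350 RPM ± 194 against 250 ± 201 in Dent, log2 difference −0.65 ± 0.22, limma adjusted p = 0.0202).

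**Figure D3:**
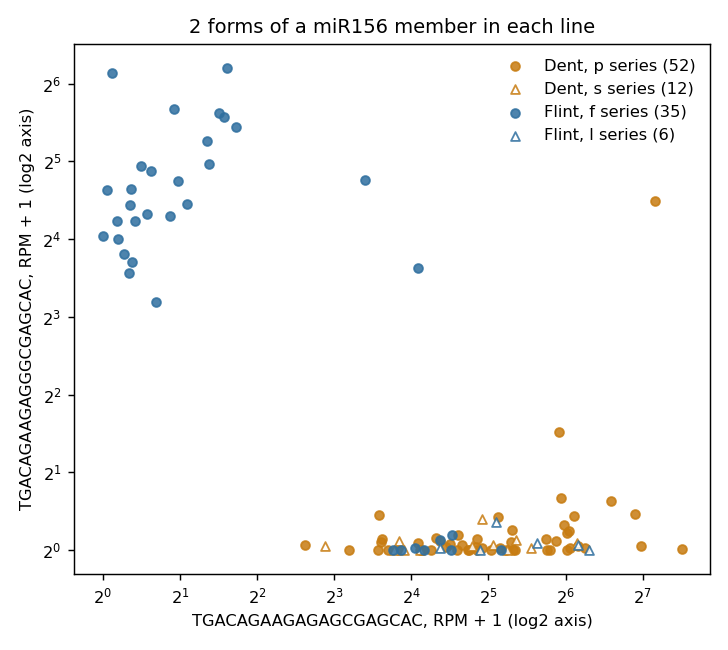
Level of the listed miR156 member TGACAGAAGAGAGCGAGCAC (x axis) against its A12G form TGACAGAAGAGGGCGAGCAC (y axis) in each of 105 lines, both as RPM + 1 on log2 axes. Lines of the f series divide between both axes, with 27 of 35 at 1 RPM or more of the A12G form, while all 6 l lines lie with the Dent lines along the x axis.

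The miRNAs were also tested as function lists, and none of these passed against other sequences. In the nutrient and copper list 4 of 7 sequences rose in Dent (miR398, miR408 and both of miR399) and 1 fell (miR397), over all sequences and adjusted over the list alone, with a median log2 difference of 0.47. Tested for a shift to the same side, this list passed (fry adjusted p = 0.0402, or 0.0546 with a pseudocount of 0.1), but not against other sequences (camera adjusted p = 0.133 with the preset correlation, adjusted p = 0.829 with an estimated correlation). In the development list 2 of 25 sequences were higher in Dent and 1 in Flint (camera adjusted p = 0.198, fry 0.352), and in the silencing pathway list 1 of 3 was higher in Dent (0.405 and 0.236). The list of all 35 miRNA sequences had a camera adjusted p of 0.110 and a fry adjusted p of 0.236, and no list passed camera with an estimated correlation (adjusted p from 0.829 to 0.899). A list of fragments of 5S and 5.8S rRNA and of 2 tRNA ends was read as a sign of RNA breakdown. Its members made up 3.36% ± 1.07 of RPM in Dent and 3.35% ± 0.908 in Flint (adjusted p = 0.969, permutation test). Of 1860 such fragments tested, 23 were higher in Dent and 86 in Flint, or 3 and 31 adjusted over the list alone (camera adjusted p = 0.615, fry adjusted p = 0.772). The list was partial. Sequences at means of 4843 and 2192 RPM that hold the whole of a listed fragment (2269 RPM) behind added 5′ bases were not on it. These results are therefore for the listed fragments alone and do not show whether RNA breakdown differed between the pools.

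Within Dent, 3758 sequences were higher in the p series and 1618 in the s series, of which 739 and 290 differed by at least 1 log2 unit (limma, 4 group means in the model). The 22-nt class was again called most often, at 10.2% of those tested against 5.67% of 24-nt and 3.59% of 21-nt sequences. Of the 35 listed miRNA sequences, 0 were called by limma (smallest adjusted p 0.153, 1 at an unadjusted p under 0.05). The following examples were picked after their values were seen, among the largest differences of sequences of 21, 22 and 24 nt at 10 RPM or more. ATAAACACACATGTGGTCTAGCGG was at 47.04 RPM ± 41.9 (SD, n = 52) in p lines and 0.936 ± 2.04 (SD, n = 12) in s lines, and GAGAAGATGTATCGTAGAGTT at 56.7 ± 73.6 and 0.948 ± 2.84. CATTCTGATTTGGTGCCCGTGA was at 157.4 RPM ± 224 in p lines and 326 ± 179 in s lines. Of the p lines 15 of 52 and of the s lines 9 of 12 had a high adapter share. With the adapter share as a covariate, 886 of the 1029 larger calls stayed, and in lines of high adapter share alone 678 stayed, while in lines of low adapter share, which held 3 s lines, 2 stayed and 18 had the opposite sign. Without the filter on low values, 5809 sequences were higher in p lines and 9232 in s lines. With first libraries alone, 854 and 665 differed by at least 1 log2 unit.

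Within Flint, 435 sequences were higher in the f series and 696 in the l series, of which 220 and 393 differed by at least 1 log2 unit. The miR156 member TGACAGAAGAGAGCGAGCAC was the 1 listed miRNA sequence called among 35. It averaged 5.77 RPM in f lines and 46.5 RPM in l lines (f minus l −3.67, limma adjusted p = 8e-06). A few of the sequences named for Dent against Flint also parted the Flint series, while most of them were not called there. GCTCACCCTCTATCTGTCAGT was at 14.3 RPM ± 41.7 (SD, n = 35) in f lines and 130 ± 114 (SD, n = 6) in l lines (limma adjusted p = 0.0017), and CAGATACTTTTGGGGCACCTGG was higher in f lines by 2.47 log2 units (limma adjusted p = 9.5e-10). TACTAGAACTGATGGACGTGG, picked after its values were seen, was at 27.1 RPM ± 22.6 in f lines and 5.01 ± 12.1 in l lines, where 1 of 6 lines reached 1 RPM. The majority of calls for the l series turned round with first libraries alone (343 and 295) and with a pseudocount of 0.1 (659 and 494). Of the 613 larger calls, 511 stayed with the adapter share as a covariate and 26.4% stayed in lines of low adapter share, which held 16 f and 4 l lines.

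Lines of a pool resembled each other more than lines of different pools. The mean Spearman correlation between lines over the sequences tested was 0.510 ± 0.129 (SD, 2016 pairs) within Dent, 0.553 ± 0.0930 (820 pairs) within Flint and 0.465 ± 0.109 (2624 pairs) between them, and the within-pool mean lay 0.0570 above the between-pool mean (permutation p = 1e-05, the smallest that 100000 resamples can give). Within adapter classes this difference was 0.0382 (low, permutation p = 0.00844) and 0.0817 (high, p = 1e-05). It was 0.0267 with Pearson's correlation (permutation p = 3e-05) and 0.0175 among sequences at 1 RPM in at least 53 lines (p = 0.00445), where Dent pairs averaged 0.514, Flint pairs 0.561 and pairs between pools 0.510. The first principal component held 16.6% of the variance and did not differ between the pools (adjusted p = 0.968, permutation test). Component 3, with 8.05%, parted them most (adjusted p = 5e-05), and component 1 correlated with the 22-nt share of a line (r = 0.80).

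**Figure D4:**
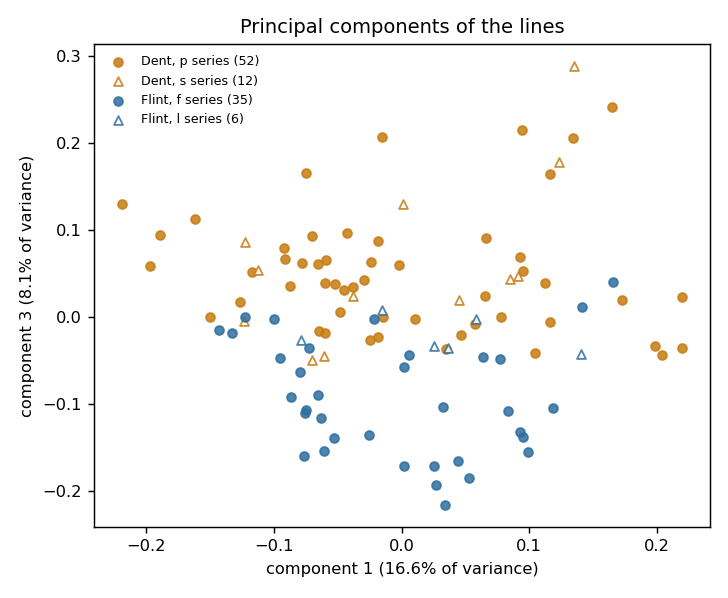
Lines placed on principal components 1 (x axis, 16.6% of variance) and 3 (y axis, 8.05%) of log2(RPM + 1) over 145521 sequences, 1 point per line. Dent lines lie mostly above Flint lines on component 3, while both pools spread over component 1.

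A second library of the same line correlated with the first at 0.542 ± 0.0817 (SD, 10 pairs, range 0.408 to 0.656), against 0.467 ± 0.0502 with lines of its own pool and 0.417 ± 0.0449 with lines of the other pool (permutation p = 0.00072). The own line was the best match in 0 of 10 cases, with ranks from 2 to 46 of 105 lines. In 7 of the 10 the libraries lay on different sides of the adapter boundary, with a mean correlation of 0.559 and ranks up to 20, against 0.504 and ranks up to 46 in the other 3. The excess over the own pool, 0.0751, was no longer past the threshold with Pearson's correlation (0.0158, permutation p = 0.231) or among sequences at 1 RPM in at least 53 lines (0.0163, permutation p = 0.327).

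Of all sequences, 0 were at 1 RPM or more in at least 50% of the lines of 1 pool and listed at 0 in every line of the other. When 1 RPM was asked of 25% of the lines, 61 sequences belonged to Dent alone and 23 to Flint alone. With values under 1 RPM allowed in the other pool, 76 sequences belonged to Dent and 219 to Flint, and in 100 splits of the lines the highest count other than the real one was 0 for both of these wider rules.

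The miRNAs miR156 and miR172 mark the juvenile and the adult phase of the shoot. Across lines they correlated in Dent (r = 0.57, permutation p = 1e-05; rho = 0.55, p = 2e-05) and in Flint (r = 0.45, p = 0.0034; rho = 0.45, p = 0.0029), 1 of 2 relations planned for each pool, with adjusted p of 2e-05 and 0.0034 for r. Without the 2 lines farthest from the median, r was 0.58 and 0.37. Families rose and fell together across lines in general, with a median rho of 0.648 in Dent and 0.570 in Flint over 231 pairs of named families, and with the mean of the other named families taken off the rho of miR156 with miR172 was 0.13 and 0.09. The listed miR172 sequence was rare, at 0.429 RPM ± 0.585 in Dent and 0.390 ± 0.477 in Flint. Within adapter classes rho was 0.61 and 0.40 in Dent at low and high share and 0.20 and 0.39 in Flint, and it did not pass in the Flint classes (permutation p = 0.407 and 0.0780) or the Dent class of high share (p = 0.0524). With all sequences that begin with the first 18 bases of a listed one, r was 0.72 in Dent and 0.68 in Flint, and in the Flint classes 0.58 (permutation p = 0.00797) and 0.53 (p = 0.0136).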

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

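The outlier values below come from a rule set before the data were examined, and the test of erroneous copies, the test of alleles, the test of a variant in the copper-linked miRNAs and the fits with adapter share or sequences at 0 were added after the data were seen.

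Within the 6 lines of the l series, 52 values were tested for a line apart from the rest, and 3 exceeded the critical ratio of gap to range, where chance gives about 1 in 20. In 1 line the 20-nt share was 8.81%, against 5.16% to 6.09% in the other lines (ratio 0.746). In the same line TACTAGAACTGATGGACGTGG stood at 4.94 on the log2(RPM + 1) scale, against 0.25 for the next line (ratio 0.9501). In a different l line CAAGAAGGGTTCTGACAGCGG stood at 6.16 on that scale, against 0.38 for the next line (ratio 0.938).

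The first pattern weighed is the number of sequences called between Dent and Flint, 34028 in all. Of 100 splits of the lines into groups of these sizes, 1, the real one, called as many, and the highest of the other splits called 783, so that a random grouping of lines can be excluded. With log2 adapter share as a covariate 99.9% of the 2741 larger calls stayed in the same direction, with the share of sequences at 0 as a covariate 100% stayed, and 86.2% stayed in lines of low (36 with the opposite sign) and 94.2% in lines of high adapter share. The pools hardly differed in adapter share (0.301% and 0.347%) or in sequences at 0 (48.8% and 49.5%), so as covariates these could remove few calls. The calls kept within adapter classes argue against the adapter share as the whole cause. Preparation effects that neither measure carries stay open. Relatedness of lines within a pool, which the design names through the pools, stays open. So does the place of 24-nt calls, whose excess in Dent turned round in lines of high adapter share and, over all lines, among calls of 1 log2 unit or more. For the series, 1 of 100 splits of Dent lines called as many sequences as p against s (5376, highest other 393, from a split whose group of 12 held 10 lines of high adapter share against 9 in the real s series) and 2 of 100 splits of Flint lines as many as f against l (1131, highest other 1246, from a split whose group of 6 held 5 lines of high adapter share against 2 in the real l series).

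The second pattern is that called sequences came in pairs that differed by 1 base and went opposite ways. Of the 2741 larger calls, 458 had a partner at 1 substitution called the other way and 123 a partner called the same way. With directions shuffled over the called sequences 1000 times, means were 266 the other way (at most 318) and 324 the same way. Many of these calls overlap, which the shuffles do not allow for. Joined by 18 shared bases on either strand, the 230 pairs called opposite ways formed 68 groups, the 3 biggest with 51.3% of the pairs, and the 82 pairs called the same way formed 26. Copies made by sequencing or PCR error follow their source across lines, whereas over groups with both members at 1 RPM or more the median Spearman correlation of members was −0.399 within Dent (30 groups, upper quartile −0.0893) and −0.287 within Flint (23 groups, −0.192), against 0.825 and 0.719 for pairs called the same way. Such copies would hardly be called opposite ways, so the choice of the opposite pairs had already left them out. The correlations of these pairs are therefore no separate test of copies. A candidate explanation is that both members are alleles of a locus at which lines differ: in 40 of 4119 pairs chosen on first libraries for a Spearman correlation under −0.5 between members, the balance of members in a second library was closest to that of its own line in 6 of 10 repeated lines, with ranks down to 13 of 105, against at most 2 of 10 in 100 draws of pairs of like abundance and 0 in 100 draws of unrelated pairs with that correlation as well, and with 1 pair from each of the 16 groups these overlap in, in 7 of 10 against at most 3 and 0. The thresholds for these pairs were set after a look at all libraries, the draws were not matched on the spread between lines, and paralogous loci present in some lines stay open, since positions in the genome were not analysed here. Over the named sequences with a partner at 1 substitution, lines with both members at 1 RPM or more ranged from 0 to 49 of 105. Alleles of 1 locus should seldom occur together in an inbred line, so alleles alone leave the high end of this range unaccounted for.

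The third pattern is that miR398 and miR408 were higher and miR397 lower in Dent. The Spearman correlation of miR398 with miR408 was 0.628 within Dent and 0.761 within Flint, where the median over pairs of families was 0.648 and 0.570. With the mean of other families removed, a step that was not part of the prediction, it was 0.599 and 0.789, the highest of 231 pairs of families in both pools. A copper-linked programme that shifts both together may account for them, but correlations within pools do not test what moved the means between pools. miR528, also copper-linked and correlated with miR408 (0.550 and 0.433 with that mean removed, rank 4 in Dent and 27 in Flint), did not differ between the pools (0.30, adjusted p = 0.362). For miR397 the correlation with miR408 was 0.114 in Dent and 0.257 in Flint (0.0763 and 0.237 with the mean removed), between the bounds set. Their differences between the pools had opposite signs, −1.51 ± 0.32 (SE) for miR397 and 0.91 ± 0.22 for miR408. This argues against 1 programme that moves both the same way as the cause of both differences. Whether such a programme adds to the level of miR397 within a pool cannot be told. A variant of the mature sequence that keeps its level is argued against, since in the pool where each was lower the 2, 5 and 1 sequences of the whole table at 1 or 2 substitutions from miR398, miR408 and miR397 held at most 0.788% of the RPM by which the pools differed, while the loss of a locus or a wider change of sequence stays open. The supply of copper to the seedlings was not measured here, and the preparation stays open for miR408 and miR397, which were each called in 1 adapter class, and in s against l lines 0 of the 3 were called.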

How the results depend on the processing

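The adapter, zero-share, relative-family and list settings and s against l lines for families in this part were chosen after the data were seen. Depth was unknown, so how far it limits a value cannot be said. No paired analysis was possible because replicate numbers were given in accession order and lines of different pools do not pair. The genome match was not run, since no genome was used here. All 42 alternatives for length shares kept the side of the threshold. Of 243 values for named sequences 232 did, and the other 11 lost the call in s against l lines alone, where the rule for naming them had fixed their direction and the difference fell as low as 0.19 (from 1.78) and −0.33 (from −3.40). Of 198 values for named families 179 did, 14 lost the call, 4 gained it, and miR399 turned to −0.084 in s against l lines. For the other changes the cause was not tested unless stated.

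For Dent against Flint, calls of 1 log2 unit or more were 10412 and 11709 with a pseudocount of 0.1 and 2329 and 4475 with 0.5, since a smaller pseudocount widens differences of rare sequences. Calls were 53122 and 65727 with no filter, and 2222 and 3926 (332 and 553 of 1 log2 unit) at 1 RPM in 53 lines, as other numbers of sequences were tested. They were 328 (222 of 1 log2 unit) and 3235 in s against l lines, 8969 and 9277 at low adapter share, and 9567 and 16020 at high adapter share, where 1616 and 4007 reached 1 log2 unit. For p against s, calls of 1 log2 unit were 5475 and 1799 with a pseudocount of 0.1, and 665 were higher in s with first libraries. Calls were 5809 and 9232 with no filter, 2053 higher in p (442 of 1 log2 unit higher in s) at high adapter share, and 0 and 28 (0 and 26 of 1 log2 unit) at low adapter share, where limma gave 7022 at an unadjusted p under 0.05. For f against l, calls were 659 higher in f, all of 1 log2 unit, with a pseudocount of 0.1, and 1001 and 8445 (691 of 1 log2 unit higher in l) with no filter. They were 295 higher in l (201 of 1 log2 unit) with first libraries, and 183 and 267 (112 and 218 of 1 log2 unit) at low adapter share.

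Sequences of 1 pool were 61 and 23 at 1 RPM in 25% of lines, and 76 and 219 with values under 1 RPM allowed in the other pool. At low adapter share 3 families were higher in Dent and 0 in Flint, at high adapter share 2 were higher in Dent, relative to other families 4 were higher in Flint, and in s against l lines 0 were higher in Dent and 0 in Flint (exact permutation test, 1 at an unadjusted p under 0.05). The excess of repeats over their pool was 0.0158 with Pearson's correlation (permutation p = 0.231) and 0.0163 with the filter of 53 lines (p = 0.327). The nutrient and copper list had a fry adjusted p of 0.0546 with a pseudocount of 0.1 (0.00948 to 0.0546 over its alternatives), and the list of all miRNAs a camera adjusted p of 0.0364 with first libraries (0.0364 to 0.135), which was 0.755 with an estimated correlation.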

Other observations

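The tests in this part were chosen after the data were seen.

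Joined by 18 shared bases, the 2741 larger calls between the pools formed 1233 groups, of which 876 held 1 sequence. The biggest held 210 sequences higher in Dent and 89 higher in Flint, with CCGTCCACGCCCGGTCGTACT as its most abundant member and lengths of 18 to 36 nt. The next held 139, 49 higher in Dent and 90 higher in Flint, with AGGATGCTGACGCAATGTGA as its most abundant member and lengths of 18 to 39 nt. Counted as groups rather than sequences, 384 groups of 22-nt calls were higher in Flint and 120 in Dent, a ratio of 3.20, against 1.53 for 21 nt and 1.46 for 24 nt. Over sequences the 22-nt ratio was 2.85 and ranged from 1.37 in lines of low adapter share to 5.804 in lines of high adapter share over the alternatives run. Among 22-nt sequences, 14.4% of the larger calls had a 1-substitution partner called the other way, against 23.9% of 21-nt and 6.78% of 24-nt calls.

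The 21-nt pair GCTCACCCTCTATCTGTCAGT (81.1 RPM in Dent, 31.3 RPM in Flint) and GCTCACTCTCTATCTGTCAGC (7.76 and 126 RPM), which differ by C7T and T21C counted from 1 at the 5′ end of the first, lie 2 and 1 edits from the passenger strand expected for a listed miR156 mature sequence with overhangs of 2 nt. Of 9949 tested 21-nt sequences, 3 lay within 1 edit and 15 within 2 edits of such a strand of any listed miRNA. Just 1 member reached 1 RPM in 99 of 105 lines, and both did in 6. In f lines the first reached 1 RPM in 7 of 35 and the second in 29. In l lines they did so in 5 and 2 of 6 lines. The f and l lines also differed in 21-nt miR156 forms: TTGACAGAAGAGGGCGAGCAC was at 18.5 RPM ± 18.5 (SD, n = 35) in f lines and 0.0370 ± 0.0433 (SD, n = 6) in l lines, and TTGACAGAAGAGAGCGAGCAC at 3.57 ± 6.33 and 27.2 ± 11.3. The passenger-like pair is not shown to be the other strand of these forms.

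Component 4 of the lines, with 6.37% of the variance, correlated with the log2 adapter share (r = −0.62) and also differed between the pools (adjusted p = 0.00035, permutation test). Pairs of lines of the same adapter class were more alike than pairs of different classes, with a mean Spearman correlation of 0.538 against 0.505 within a pool and 0.483 against 0.448 between pools.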
